A study of Homo sapiens with 15 samples.

How the data were processed

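Total RNA from A549 cells, a human lung carcinoma line, was measured on 15 Affymetrix HG-U133 Plus 2.0 arrays, in 5 groups of 3. The groups were vehicle for 24 h, geldanamycin at 40 nM for 24 h, vehicle for 48 h, geldanamycin at 10 nM for 48 h and geldanamycin at 40 nM for 48 h. Geldanamycin binds the ATP pocket of the chaperone HSP90. Per the labels, 40 nM and 10 nM were the doses found as IC50 and IC20, the vehicle was DMSO at 0.4% and cells attached for 24 h before treatment.

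The values are log2 expression values as the authors deposited them, 1 per probe set and array, made by RMA in Affymetrix Expression Console per the submitters' processing notes; the version is not given in the sources used here. RMA subtracts background, makes the distributions of the arrays alike by quantiles and summarises the probes of a set. The mean log2 value over all probe sets was 5.13 on the vehicle arrays at 24 h and 5.52 on those at 48 h, and differed little within a time, so the arrays of each time appear to have been normalized in a run of their own. Differences within a time are therefore on 1 scale, while a level at 48 h set against a level at 24 h also holds any step between the runs. The effect of 40 nM at 48 h minus that at 24 h is a difference of differences, in which a step shared by the arrays of a time drops out. On arrays there is no read depth; the number of arrays limits the precision, and the median standard error of a log2 difference between 2 groups was 0.097.

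The table holds 54675 probe sets, of which 62 are controls. The platform annotation gave 41091 other probe sets 1 gene symbol, 1801 several, and 11721 are unnamed here. Symbols were updated through the gene ID for 41043 of the 41091. For each of 19775 genes, the single-symbol probe set with the highest mean over the 15 arrays was used, and probe sets with several symbols named no gene. HSPA1A and HSPA8 were not measured by a probe set with a single symbol.

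Group means were fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which pools the spread over the 5 groups with 10 residual degrees of freedom. The comparisons were 40 nM with vehicle at each time, 10 nM with vehicle at 48 h, 40 nM with 10 nM at 48 h, vehicle at 48 h with vehicle at 24 h, and the difference between the effects of 40 nM at 48 h and at 24 h. P-values were two-sided, adjusted by Benjamini-Hochberg over the 19775 genes, with a threshold of 0.05. All "±" values of log2 changes are standard errors of this fit, with 3 arrays per group. The labels do not say that the replicates came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

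Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists. They were the heat shock response, HSP90 clients (transcripts), the unfolded protein response of the endoplasmic reticulum, the amino acid response (ATF4 targets), NRF2 targets, p53 targets, G1/S and DNA replication, G2/M and mitosis, apoptosis regulators, proteasome subunits, autophagy and lysosome, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, mesenchymal and TGF-beta genes, epithelial junction and keratin genes, NF-kB and inflammatory genes, interferon-stimulated genes, ERK pathway output, glucocorticoid receptor targets, actin and SRF targets, and markers of alveolar type 2 cells, fibroblasts, leukocytes and endothelium. Some genes are on 2 lists, such as BAX, SLC7A11 and SESN2. An estimated correlation and the fry test were run as alternatives; fry asks whether a list's genes move on balance one way and does not compare them with other genes.

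The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names, in each comparison with vehicle, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, and for the other comparisons the 5 largest each way; up to 4 passing members of each called list with the largest change; and HSP90AA1, HSP90AB1, HSP90B1, TRAP1, HSF1, DNAJB1 and HSPB1 against vehicle. There are 2 exceptions. No genes are named for the vehicle comparison, because of the possible step between the runs, and genes named outside the rule are said to have been chosen after their values were seen. Names that only give a locus were counted but not described.

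The alternatives were cyclic loess between arrays, array medians subtracted, a floor at the 20th percentile, the dimmest 40% of genes left out and the mean of a gene's probe sets. In another, probe sets with names ending in _x_at or _s_at were left out. A gene that lost its probe set was read from its brightest remaining one, or not measured, and binding to other genes was not tested. Further alternatives were the replicate number as a block, an intensity trend with a robust prior, array weights, the compared groups alone, a 2-fold threshold, and each array left out in turn. Those chosen after seeing the data were quantile normalization of all arrays together, fits without the 10 nM arrays, and fits without the 526 genes whose vehicle arrays differed between the times by 1 or more on the log2 scale after centring.

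The fit was tested on simulated data made from the 24 h comparison of 40 nM with vehicle, with 19775 genes and 50 changed genes of each size. It recovered 10% of changes of 0.25 on the log2 scale, 68% of 0.5, 98% of 1 and 100% of 2, and 3.5% of its calls were false. With no effect simulated, the list test made 0 calls over 26 lists in 6 comparisons. The simulated genes varied independently of each other, so this does not show how the test behaves for lists whose genes vary together. In the real data the estimated correlation was 0.36 for G2/M and for G1/S genes, and 0.38 for p53 targets. The lowest and highest correlations between an array and the others of its group were 0.994 and 0.998, and 0 pairs of arrays in a group were identical throughout.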

Results

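Gene expression was measured in the lung carcinoma line A549 after exposure to geldanamycin, an inhibitor of the chaperone HSP90, or to vehicle. There were 3 arrays in each of 5 groups: vehicle and 40 nM at 24 h, and vehicle, 10 nM and 40 nM at 48 h. Values are log2 RMA values for 19775 genes, and the 40 nM and 10 nM doses are the IC50 and the IC20 that the labels give. The series title names a method of latent pathway analysis, and the comparisons address how expression in these cells changed with dose and time.

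The 10 nM arrays differed from the other arrays in their control probe sets. Poly-A spike controls, bacterial transcripts that are added to RNA before labelling, had a mean log2 value of 3.37 ± 0.04 (SD, n = 3) on the 10 nM arrays and 5.93 ± 0.06 on the vehicle arrays at 48 h. Over 24 such probe sets the median log2 difference between 10 nM and vehicle was -2.02, and the lowest was -6.59. Most of these probe sets lay near background at 10 nM (dap 3' at 2.59), so such differences are lower bounds in size. The 18 hybridization controls, which are added after labelling, had a median difference of 0.29. The 5' control probe set of ACTB stood at 11.02 ± 0.01 at 10 nM and 13.74 ± 0.06 in vehicle, and its 3' minus 5' difference was 2.68 ± 0.03 against 0.35 ± 0.06. For GAPDH that difference was 0.13 ± 0.004 against 0.15 ± 0.03. In the 40 nM comparisons the median poly-A difference was 0.016 at 24 h and -0.11 at 48 h.

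**Figure D1:**
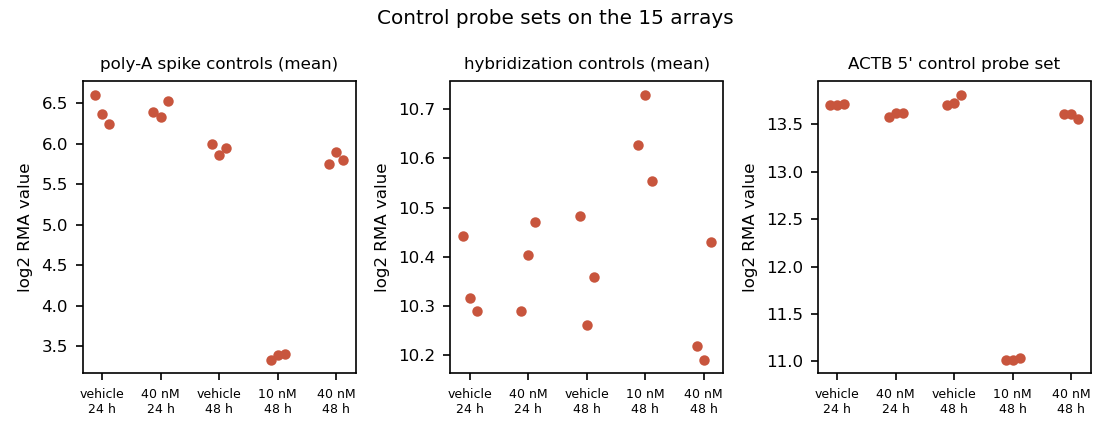
Log2 RMA values of control probe sets on each of the 15 arrays, by group: the mean of the poly-A spike controls, the mean of the hybridization controls, and the 5' probe set of ACTB. Each point is an array. The 3 arrays at 10 nM lie at 3.37 on average for the poly-A controls, against 5.81 to 6.42 for the means of the other groups.

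After 24 h at 40 nM, A549 cells had lower transcripts for the cell cycle and the amino acid response list, and higher transcripts for chaperones and NRF2 targets. All 27 measured genes of G2/M and mitosis fell, as did 28 of 29 of G1/S and DNA replication, with median log2 changes of -0.87 and -0.76. The heat shock list rose with a median of 0.52 over 25 genes and the NRF2 targets with a median of 0.69 over 24. HPD, an enzyme of tyrosine breakdown, had the largest rise, from 4.37 ± 0.48 to 8.30 ± 0.16 (SD, n = 3 arrays per group), or 15.3-fold. KLF2, a transcription factor induced by flow in endothelium, had the largest fall, by 2.61 ± 0.15 on the log2 scale. Read from another probe set, without _x_at and _s_at ones, it was not called (-0.10, limma adjusted p = 0.65).

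In all, 6222 of the 19775 genes changed at 24 h (limma, adjusted p below 0.05), 2927 higher and 3295 lower, and 320 rose and 228 fell at least 2-fold. The groups did not overlap for 5997 of the 6222. These genes had been called on the same arrays, and a called gene seldom overlaps. Such counts, here and below, therefore describe the called genes and are no further evidence of an effect. Other large rises were those of TM4SF4 (3.64 ± 0.09), the vitamin C transporter SLC23A1 (3.62 ± 0.15), the glutathione peroxidase GPX2 (3.48 ± 0.07), AGR2, a protein disulfide isomerase of secretory epithelia (3.29 ± 0.06), and the chemokine CCL26 (3.01 ± 0.13). They also included SCARA5 (2.94 ± 0.12), the cell cycle inhibitor CDKN1C (2.81 ± 0.13), CDH1, which encodes E-cadherin (2.80 ± 0.06), and the fatty acid hydroxylase CYP4F3 (2.77 ± 0.15). Falls included PLPP4 (-2.57 ± 0.14), the ecto-nucleotidase NT5E (-2.54 ± 0.11), FOXD1 (-2.32 ± 0.06), the non-coding DLEU2 (-2.19 ± 0.12), MARCHF4 (-2.18 ± 0.10), G0S2 (-2.16 ± 0.10), CORO2B (-2.14 ± 0.10), the vitamin D receptor VDR (-2.12 ± 0.07) and the immediate early gene EGR1 (-2.11 ± 0.07).

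Of the heat shock genes at 24 h, 19 rose, 2 fell and 4 did not pass, with 19 and 2 adjusted over the list alone. The small heat shock protein genes HSPB8 and HSPB1 rose by 1.998 ± 0.07 and 1.33 ± 0.06, and the HSP70 family members HSPA4L and HSPA2 by 1.39 ± 0.11 and 1.35 ± 0.08. The HSP90 genes rose less: HSP90AB1 by 0.53 ± 0.05, HSP90B1 of the endoplasmic reticulum by 0.33 ± 0.09 and HSP90AA1 by 0.30 ± 0.05. HSP90B1 no longer passed without replicate 3 of the vehicle (adjusted p = 0.0504) or replicate 2 of the 40 nM arrays (0.057). HSF1, the transcription factor of the heat shock response, fell by 0.24 ± 0.06, a call lost with the arrays of the compared groups alone (adjusted p = 0.058). DNAJB1 (-0.05 ± 0.06, adjusted p = 0.60) and the mitochondrial TRAP1 (-0.15 ± 0.06, adjusted p = 0.086) did not pass in limma's test, although TRAP1 passed with array weights (adjusted p = 0.015), with an intensity trend and a robust prior (0.018), without the dimmest 40% of genes (0.039), with the floor (0.044) and without replicate 2 of the 40 nM arrays (0.038). Among NRF2 targets, which serve redox defence, 20 rose and 0 fell (21 and 1 adjusted over the list alone). Heme oxygenase HMOX1 rose by 1.67 ± 0.06, the efflux pump ABCC2 by 1.39 ± 0.07, PIR by 1.11 ± 0.06 and AKR1C2 by 1.10 ± 0.06.

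In the amino acid response list, 20 of 25 genes fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -0.73. Asparagine synthetase ASNS fell by 1.86 ± 0.06, CBS of transsulfuration by 1.67 ± 0.08 and PHGDH of serine synthesis by 1.42 ± 0.06, whereas CTH, the next enzyme after CBS, rose by 2.36 ± 0.13. The counts for the cell cycle lists were the same adjusted over the list alone, 27 and 28 falls. The ribonucleotide reductase subunit RRM2 fell by 1.73 ± 0.05, MCM10 by 1.14 ± 0.09, GINS2 by 1.11 ± 0.08 and cyclin CCNE2 by 1.07 ± 0.10. Of the mitotic genes, the kinase AURKB fell by 1.55 ± 0.06, DLGAP5 by 1.27 ± 0.08, and the kinesin KIF23 and cyclin CCNA2 both by 1.21 (SE 0.07 and 0.08). Among epithelial junction and keratin genes 12 rose and 3 fell of 23 (12 and 4 adjusted over the list alone), median 0.24, with plakoglobin JUP at 2.34 ± 0.07, claudin CLDN2 at 1.34 ± 0.08 and keratin KRT7 lower at -0.90 ± 0.05.

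A further 7 lists were called at 24 h with the preset correlation, and the call of each was lost with an estimated one. Of 23 p53 targets 15 rose and 3 fell (16 and 3 adjusted over the list alone), median 0.54; the adjusted p = 0.24 with an estimated correlation. ZMAT3 rose by 1.33 ± 0.08, CCNG1 by 1.08 ± 0.07 and SESN1 by 0.94 ± 0.08, and SESN2 fell by 0.90 ± 0.06. Of 21 NF-kB and inflammatory genes 13 rose and 2 fell (15 and 3 over the list alone), median 0.46, and the adjusted p = 0.087 with an estimated correlation. The prostaglandin synthase PTGS2 rose by 2.07 ± 0.14, and the chemokines CCL2 and CCL20 by 1.68 ± 0.09 and 1.53 ± 0.10, while the cytokine IL11 fell by 1.71 ± 0.06. Of 23 interferon-stimulated genes 14 rose and 1 fell (16 and 2 over the list alone), median 0.49, with adjusted p = 0.24 with an estimated correlation. ISG20 rose by 1.98 ± 0.10, IFIT1 by 1.53 ± 0.11, IFIT3 by 1.41 ± 0.14 and BST2 by 1.40 ± 0.22. Of 21 genes of ERK pathway output 15 fell and 3 rose (15 and 4 over the list alone), median -0.61, with adjusted p = 0.052 with an estimated correlation. Beside EGR1, ETV5 fell by 1.96 ± 0.07, FOSL1 by 1.93 ± 0.09 and FOS fell by 1.901 ± 0.12.

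The remaining calls at 24 h were smaller. Autophagy and lysosome genes had 15 rises and 4 falls of 24 (15 and 4 adjusted over the list alone), median 0.29, adjusted p = 0.32 with an estimated correlation. GABARAPL1 rose by 1.33 ± 0.15, WIPI1 by 0.85 ± 0.11, SQSTM1 by 0.64 ± 0.05 and OPTN by 0.61 ± 0.06. Of 23 oxidative phosphorylation genes 11 rose and 0 fell (11 and 0 over the list alone), median 0.15, adjusted p = 0.22 with an estimated correlation, with SDHC at 0.37 ± 0.07 and NDUFV2 at 0.33 ± 0.07. Of 23 actin and SRF target genes 9 fell and 3 rose (10 and 3 over the list alone), median -0.16, adjusted p = 0.16 with an estimated correlation. The tropomyosins TPM4 and TPM1 fell by 0.83 ± 0.08 and 0.49 ± 0.05, profilin PFN1 by 0.51 ± 0.05 and SRF by 0.50 ± 0.08. The 6 lists whose call held at 24 h with an estimated correlation were heat shock, amino acid response, NRF2 targets, G1/S, G2/M and epithelial genes. Without _x_at and _s_at probe sets the epithelial call ended (median -0.027, camera adjusted p = 0.35). Those for the NF-kB list and oxidative phosphorylation ended too (both adjusted p = 0.065). The same alternative ended the calls of KLF2, DLEU2, ASNS, GINS2, TPM1, HSPB8, KIF23 and KRT7, whose other probe sets gave changes between -0.42 and 0.13.

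The other 13 lists were not called at 24 h. HSP90 clients had 10 rises and 8 falls of 27 (11 and 8 adjusted over the list alone), the unfolded protein response 3 and 10 of 25 (5 and 10), apoptosis regulators 8 and 5 of 20 (8 and 5), proteasome subunits 1 and 8 of 27 (1 and 8), cholesterol synthesis 2 and 5 of 17 (2 and 6), and glycolysis and hypoxia 11 and 6 of 25 (11 and 7). Ribosomal proteins had 1 rise and 0 falls of 23 (0 and 0), mesenchymal genes 5 and 11 of 24 (6 and 11), and glucocorticoid receptor targets 4 and 8 of 17 (4 and 8). Of the cell type markers, alveolar type 2 genes had 1 rise and 1 fall of 13 (1 and 1), fibroblast markers 3 and 0 of 12 (3 and 0), leukocyte markers 0 and 0 of 12 (0 and 0), and endothelial markers 0 and 0 of 11 (0 and 0). Their medians lay between -0.17 and 0.089, and median, mean and test differed in sign for the HSP90 clients, the alveolar type 2 markers and the leukocyte markers.

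**Figure D2:**
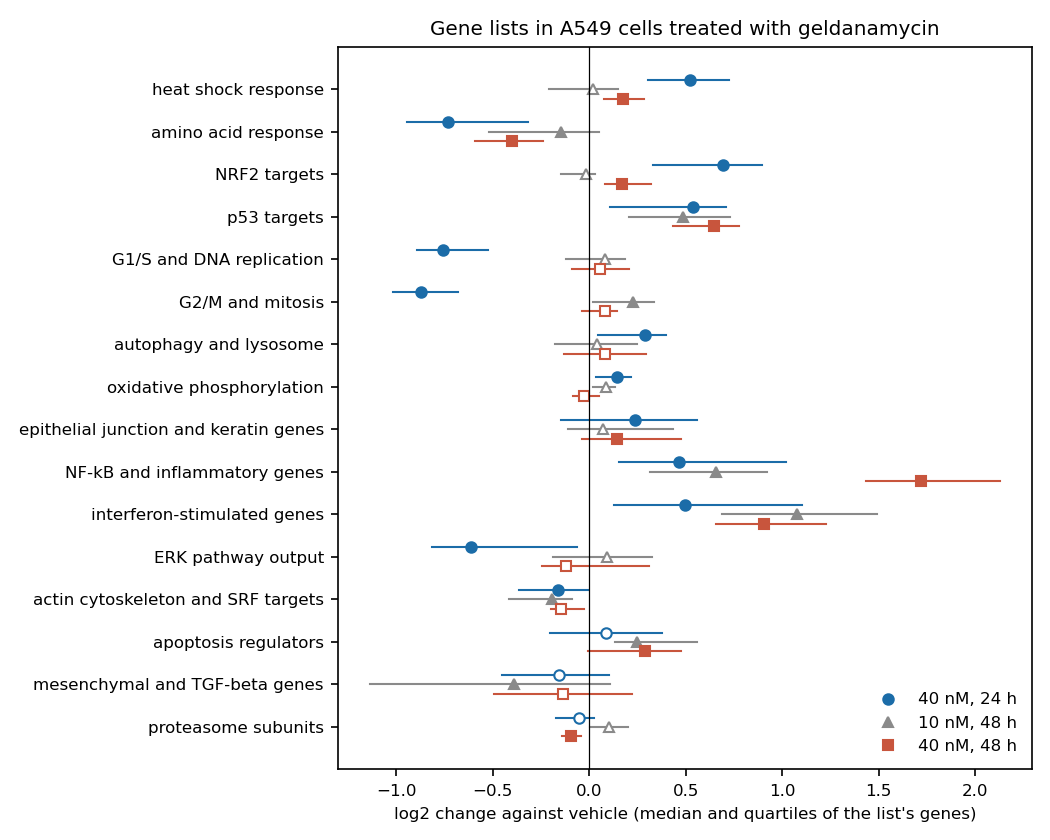
Median log2 change against vehicle, with lines from the first to the third quartile of each list's genes, for lists called in at least 1 of the 3 comparisons with vehicle. Filled symbols are lists called with the preset correlation and open symbols lists that were not. The G2/M median was -0.87 at 24 h and 0.081 at 48 h at 40 nM, and the NF-kB median was 0.46 and 1.72.

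After 48 h at 40 nM, inflammatory genes were the group with the largest rise. All 21 measured NF-kB and inflammatory genes rose, with a median log2 change of 1.72, and 20 of 23 interferon-stimulated genes rose, with a median of 0.91. The chemokine CCL20 rose from 7.60 to 11.02, by 3.42 ± 0.10, or 10.7-fold (n = 3 arrays per group), and CCL2 by 3.19 ± 0.09. The p53 targets rose with a median of 0.65, and the amino acid response fell with a median of -0.40. The BMP antagonist GREM1 had the largest fall, by 2.72 ± 0.13.

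At 48 h and 40 nM, 4207 genes changed (limma), 2085 higher and 2122 lower, with 195 rises and 45 falls of at least 2-fold. For 4177 of these called genes the groups did not overlap. The largest rises further included COXFA4L3 (3.37 ± 0.11), the chemokine CCL5 (2.98 ± 0.12), the anti-apoptotic BCL2A1 (2.81 ± 0.15), the adhesion molecule VCAM1 (2.67 ± 0.15), GPX2 (2.60 ± 0.07), the cytokine subunit EBI3 (2.60 ± 0.16), TM4SF4 (2.56 ± 0.09) and TM4SF20 (2.54 ± 0.22). EGR1 fell by 2.65 ± 0.07, KLF2 by 2.47 ± 0.15, SCG5 by 2.38 ± 0.19, FOS by 2.28 ± 0.12, RAB39B by 1.74 ± 0.08, PLPP4 by 1.68 ± 0.14, the receptor kinase AXL by 1.44 ± 0.05, RBMS3 by 1.44 ± 0.13 and the stress gene NUPR1 by 1.43 ± 0.10. PTGS2 rose by 2.48 ± 0.14 and the cytokine IL1A by 2.19 ± 0.14, and all 21 rises of this list passed adjusted over the list alone. Of the interferon-stimulated genes, IFI44L rose by 1.78 ± 0.12, the RNA sensor IFIH1 by 1.60 ± 0.19, IFIT3 by 1.57 ± 0.14 and IFIT1 by 1.35 ± 0.11 (20 rises adjusted over the list alone).

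Of 23 p53 targets at 48 h, 19 rose and 1 fell (21 and 1 adjusted over the list alone). GDF15 rose by 1.45 ± 0.07, the cell cycle inhibitor CDKN1A by 1.38 ± 0.06, the death receptor FAS by 1.31 ± 0.08 and the p53 ligase MDM2 by 1.08 ± 0.07. In the amino acid response list 20 of 25 fell and 1 rose (21 and 2 over the list alone): beside NUPR1, TRIB3 fell by 1.20 ± 0.05, VLDLR by 0.84 ± 0.07 and CBS by 0.77 ± 0.08. Of 24 NRF2 targets 12 rose and 1 fell (17 and 2 over the list alone), median 0.17, with HMOX1 at 1.23 ± 0.06, PIR at 0.68 ± 0.06, glutathione reductase GSR at 0.42 ± 0.09 and the cystine transporter SLC7A11 lower at -0.44 ± 0.05. Of 23 epithelial genes 11 rose and 1 fell (11 and 3 over the list alone), median 0.15, with CDH1 at 1.78 ± 0.06, CLDN2 at 1.47 ± 0.08, and JUP and the laminin LAMB3 at 1.32 (SE 0.07 and 0.11). These 6 calls, of NF-kB, interferon, p53, amino acid, NRF2 and epithelial genes, held with an estimated correlation.

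A further 3 calls at 48 h and 40 nM did not hold. Of 25 heat shock genes 9 rose and 0 fell (11 and 0 adjusted over the list alone), median 0.18, adjusted p = 0.13 with an estimated correlation. HSPB8 rose by 1.25 ± 0.07, HSPA4L by 0.99 ± 0.11, CHORDC1 by 0.48 ± 0.06 and the co-chaperone FKBP4 by 0.41 ± 0.07. HSF1 fell by 0.27 ± 0.06, and HSPB1 (0.090 ± 0.06), HSP90AB1 (0.091 ± 0.05), HSP90AA1 (0.079 ± 0.05), HSP90B1 (0.00053 ± 0.09), TRAP1 (-0.078 ± 0.06) and DNAJB1 (-0.076 ± 0.06) did not pass. With the mean of its probe sets HSF1 no longer passed (-0.17, adjusted p = 0.063) and HSP90AB1 did (0.25, adjusted p = 0.0071). Both HSP90AB1 and HSP90AA1 passed with the floor (0.0037 and 0.022) and with an intensity trend and a robust prior (0.0087 and 0.016). Of 20 apoptosis regulators 10 rose and 0 fell (11 and 0 over the list alone), median 0.29, adjusted p = 0.13 with an estimated correlation. The pro-apoptotic BID was at 1.11 ± 0.06, the inhibitor BIRC2 at 0.58 ± 0.07, PMAIP1 at 0.55 ± 0.06 and BCL2L11 at 0.52 ± 0.08 (0.10, adjusted p = 0.32, with the mean of its probe sets). Of 27 proteasome subunits 5 fell and 0 rose (7 and 0 over the list alone), median -0.094, adjusted p = 0.65 with an estimated correlation. PSMC3 fell by 0.35 ± 0.06, PSMB6 by 0.22 ± 0.05, PSMC4 by 0.21 ± 0.05 and PSMB3 by 0.17 ± 0.05. The last 2 no longer passed with array medians subtracted (adjusted p = 0.059 and 0.0998), nor did PSMB3 in 2 fits that left out an array (0.066 and 0.058). The other 17 lists had medians between -0.15 and 0.089 and adjusted p-values of 0.052 or more, and median, mean and test differed in sign for ribosomal proteins, alveolar type 2 and leukocyte markers. Without _x_at and _s_at probe sets the calls of KLF2, GDF15, HSPB8, CHORDC1 and IL1A ended, with changes between -0.22 and 0.31. The proteasome call ended there too (camera adjusted p = 0.99). It also ended with the mean of a gene's probe sets (median -0.041, adjusted p = 0.52) and without replicate 1 of the 40 nM arrays (adjusted p = 0.067).

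**Figure D3:**
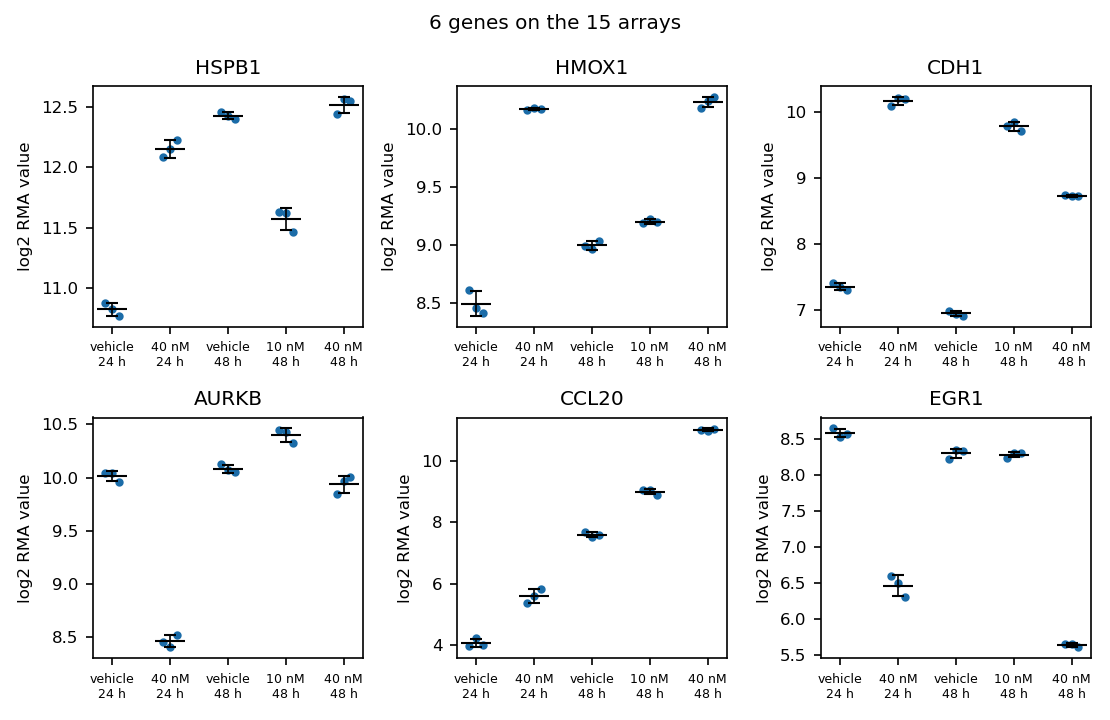
Log2 RMA values of HSPB1, HMOX1, CDH1, AURKB, CCL20 and EGR1 on the 15 arrays, by group. Points are arrays, and the horizontal line and bars are the mean and SD of 3 arrays. Levels at 24 h and 48 h appear to come from separate normalization runs. CDH1 was higher than in vehicle by 2.80 at 24 h and by 1.78 at 48 h at 40 nM, and AURKB was lower at 24 h by 1.55.

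The effects of 40 nM at the 2 times were compared directly. At 48 h cell cycle genes were higher, relative to their vehicle, than they were at 24 h. All 29 G1/S and all 27 G2/M genes passed this test of the difference, with medians of 0.75 and 0.91, and the same numbers passed adjusted over the list alone. NF-kB genes had a median difference of 1.18, with 18 of 21 higher (18 over the list alone), and NRF2 targets a median of -0.44, with 17 of 24 lower (18 over the list alone). These 4 calls held with an estimated correlation. In all, 3420 genes differed between the effects (limma), 1816 higher and 1604 lower at 48 h, of which 222 and 143 by at least 2-fold.

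The pentraxin PTX3 had the largest positive difference of effects, 3.33 ± 0.16, followed by CCL5 (2.96 ± 0.17), MAFF (2.82 ± 0.17), G0S2 (2.73 ± 0.14) and BCL2A1 (2.72 ± 0.21). PTX3 fell by 0.857 at 24 h and was higher by 2.48 at 48 h. The largest negative differences were those of HPD (-3.43 ± 0.27), GREM1 (-2.79 ± 0.18), CDKN1C (-2.53 ± 0.18), the glucuronosyltransferase UGT1A6 (-2.52 ± 0.28) and CTH (-2.47 ± 0.18). RRM2 differed by 2.06 ± 0.07, CCNE2 by 1.62 ± 0.14, MCM10 by 1.13 ± 0.13, GINS2 by 1.09 ± 0.11, AURKB by 1.41 ± 0.08, DLGAP5 by 1.32 ± 0.11, KIF23 by 1.31 ± 0.10 and CCNA2 by 1.19 ± 0.11. Of the inflammatory genes, IL11 differed by 2.37 ± 0.08, IL1A by 2.34 ± 0.20, IL6 by 2.02 ± 0.10 and CCL20 by 1.89 ± 0.15. Among NRF2 targets ABCC2 differed by -1.19 ± 0.10, AKR1C2 by -0.95 ± 0.09, OSGIN1 by -0.73 ± 0.10 and AKR1C1 by -0.69 ± 0.08.

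A further 9 lists differed between the times with the preset correlation and not with an estimated one. Heat shock genes had a median difference of -0.31 with 14 of 25 lower and 1 higher (17 and 1 adjusted over the list alone), adjusted p = 0.065 with an estimated correlation, led by HSPB1 (-1.24 ± 0.09), HSPA2 (-1.02 ± 0.11), HSPB8 (-0.75 ± 0.11) and DNAJB6 (-0.70 ± 0.13). The amino acid response had a median of 0.32 with 13 of 25 higher and 3 lower (15 and 5), and ERK pathway output 0.42 with 11 of 21 higher and 1 lower (12 and 2), both with adjusted p = 0.065 with an estimated correlation. ASNS differed by 1.20 ± 0.08, CBS by 0.90 ± 0.12 and ATF5 by 0.86 ± 0.12, and in the ERK list FOSL1 by 1.81 ± 0.13, ETV5 by 1.32 ± 0.10, the receptor EPHA2 by 1.11 ± 0.09 and IER3 by 1.02 ± 0.08. The p53 targets (median 0.20, 10 higher and 3 lower of 23, 11 and 3 over the list alone), interferon-stimulated genes (0.40, 12 and 3 of 23, 14 and 4) and apoptosis regulators (0.22, 6 and 1 of 20, 7 and 1) each had adjusted p = 0.48 with an estimated correlation. Examples were GDF15 (1.24 ± 0.10), GADD45A (1.16 ± 0.10), TNFRSF10B (0.78 ± 0.11) and CDKN1A (0.73 ± 0.08) for p53, PSMB9 (1.31 ± 0.08), ISG20 (-1.30 ± 0.14), IFI35 (1.10 ± 0.11) and BST2 (-1.09 ± 0.31) for interferon, and CASP9 (-0.88 ± 0.13), CFLAR (0.81 ± 0.12), PMAIP1 (0.73 ± 0.08) and BIRC2 (0.61 ± 0.09) for apoptosis.

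Autophagy and lysosome genes had a median difference of -0.11, with 2 higher and 6 lower of 24 (2 and 7 adjusted over the list alone), adjusted p = 0.62 with an estimated correlation, led by GABARAPL1 (-1.06 ± 0.21), WIPI1 (-0.88 ± 0.15), ULK1 (-0.76 ± 0.12) and TFEB (-0.43 ± 0.11). Cholesterol synthesis had 0.18, with 5 of 17 higher and 0 lower (8 and 0), adjusted p = 0.40 with an estimated correlation. INSIG1 was at 1.31 ± 0.12, DHCR7 at 0.47 ± 0.13, EBP at 0.42 ± 0.08 and IDI1 at 0.38 ± 0.09. Oxidative phosphorylation had -0.11, with 6 of 23 lower and 0 higher (6 and 0), adjusted p = 0.24 with an estimated correlation. SDHC was at -0.43 ± 0.10, NDUFA9 at -0.35 ± 0.09, NDUFB8 at -0.31 ± 0.07 and NDUFB5 at -0.29 ± 0.07. The other 13 lists were not called, and median, mean and test differed in sign for the proteasome, glycolysis and epithelial lists. Without _x_at and _s_at probe sets 7 of the 13 list calls were made. The differences of ASNS (-0.23), AKR1C2 (0.34) and GINS2 (-0.047) then had the other sign and did not pass (limma adjusted p = 0.087, 0.23 and 0.95). The calls of HSPB8, GDF15, KIF23, CASP9, SDHC and IL1A ended with differences between -0.26 and 0.17, while EBP (0.36) and IDI1 (0.33) were about as large and no longer passed. With the mean of a gene's probe sets EBP (0.14, adjusted p = 0.32), IDI1 (0.33, adjusted p = 0.057), SDHC (-0.19, adjusted p = 0.18) and TFEB (-0.23, adjusted p = 0.11) did not pass. With array medians subtracted TFEB (adjusted p = 0.054), NDUFA9 (0.063), DHCR7 (0.068) and NDUFB5 (0.11) did not. The autophagy call was kept in 7 of 12 fits that left out an array (camera adjusted p = 0.12 without replicate 3 of the 24 h vehicle). It was lost without the dimmest 40% of genes (0.073) and with fry (0.056). The apoptosis call was lost without replicate 1 of the 24 h vehicle (camera adjusted p = 0.070), without the dimmest 40% of genes (0.073) and with loess (0.0501). Those of DHCR7 and BST2 were lost in 6 and 5 of the fits that left out an array. The times also differ in their cultures, which a test on these arrays does not separate from time.

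Between the comparisons of 40 nM with vehicle at 24 h and at 48 h, which have vehicle arrays of their own, 2461 genes were called in the same direction, 1234 higher and 1227 lower, where independent lists of these lengths would share 309 and 354. Another 306 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 changes had Pearson r = 0.53 and Spearman rho = 0.42. Without _x_at and _s_at probe sets, the shared calls numbered 1625. CDH1, GPX2 and TM4SF4 were among the shared rises, and KLF2, EGR1 and PLPP4 among the shared falls.

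At 10 nM for 48 h, interferon-stimulated genes had the highest median log2 change of the 26 lists. Of 23 such genes 22 rose, with a median of 1.07 (camera adjusted p = 1.09e-20, and adjusted p = 0.090 with an estimated correlation). IFI27 rose by 4.18 ± 0.16 and IFI6 by 3.37 ± 0.09. The integrin ligand EDIL3 rose from 5.81 to 10.4, by 4.64 ± 0.08, or 24.9-fold (n = 3 arrays per group), and the sialyltransferase ST6GAL2 fell by 4.24 ± 0.12. The 10 nM arrays are also those whose poly-A controls had a median difference of -2.02 from vehicle, which holds for each 10 nM value given here. Across genes, the 10 nM changes had Pearson r = -0.51 with the vehicle difference of 48 h minus 24 h. For 40 nM at 48 h, r was 0.039. Both pairs share the 48 h vehicle arrays, whose noise alone lowers r. An effect of 10 nM is thus not separated here from whatever else sets these arrays apart. In the 24 h vehicle arrays, which appear to have been normalized apart, EDIL3 stood at 10.2 and ST6GAL2 at 2.87, against 10.4 and 2.94 at 10 nM and 5.81 and 7.18 in vehicle at 48 h.

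At 10 nM 5204 genes changed (limma), 2851 higher and 2353 lower, with 258 rises and 212 falls of at least 2-fold. The groups did not overlap for 5148 of these called genes. Further rises were COXFA4L3 (4.41 ± 0.11), VCAM1 (4.10 ± 0.15), the matrix protein SPARC (3.996 ± 0.08), the embryonic globin HBE1 (3.72 ± 0.09), CCL5 (3.69 ± 0.12), SHROOM2 (3.60 ± 0.10) and the formyl peptide receptor FPR2 (3.52 ± 0.10). Falls were those of cadherin CDH6 (-4.19 ± 0.10), CNKSR2 (-3.76 ± 0.09), TSPAN7 (-3.65 ± 0.12), the Y-linked ribosomal protein gene RPS4Y1 (-3.64 ± 0.11), GREM1 (-3.63 ± 0.13), the proteoglycan LUM (-3.45 ± 0.15), cystatin CSTA (-3.40 ± 0.13), RNF128 (-3.19 ± 0.16) and the monocarboxylate transporter SLC16A7 (-3.11 ± 0.12). ST6GAL2, GREM1, LUM, RNF128 and SLC16A7 lay between 2.904 and 3.13 at 10 nM, near background, so their falls are lower bounds in size. No list call at 10 nM held with an estimated correlation.

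The interferon list had 22 rises adjusted over the list alone as well. IFI44L rose by 2.22 ± 0.12 and BST2 by 1.82 ± 0.22. NF-kB genes had 16 rises and 1 fall of 21 (16 and 2 over the list alone), median 0.66, adjusted p = 0.090 with an estimated correlation. TNFAIP3 was at 1.85 ± 0.09, PTGS2 at 1.48 ± 0.14, CCL20 at 1.40 ± 0.10 and CCL2 at 1.15 ± 0.09. The p53 targets had 18 rises and 0 falls of 23 (19 and 1), median 0.49, adjusted p = 0.17 with an estimated correlation. FAS was at 1.46 ± 0.08, GDF15 at 1.37 ± 0.07, BAX at 0.87 ± 0.09 and MDM2 at 0.83 ± 0.07. Apoptosis regulators had 11 rises and 0 falls of 20 (13 and 0), median 0.25, adjusted p = 0.17 with an estimated correlation, with BCL2L11 at 1.21 ± 0.08, BID at 0.71 ± 0.06 and PMAIP1 at 0.69 ± 0.06. G2/M genes had 14 rises and 0 falls of 27 (16 and 0), median 0.23, adjusted p = 0.42 with an estimated correlation. AURKA was at 0.70 ± 0.08, UBE2C at 0.66 ± 0.05, PTTG1 at 0.64 ± 0.05 and NUSAP1 at 0.52 ± 0.07.

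Mesenchymal and TGF-beta genes had 5 rises and 15 falls of 24 at 10 nM (5 and 15 adjusted over the list alone), median -0.39, adjusted p = 0.26 with an estimated correlation. SPARC rose, while TAGLN fell by 2.63 ± 0.09, ZEB2 by 1.73 ± 0.14 and THBS1 fell by 1.504 ± 0.08. Actin and SRF targets had 2 rises and 10 falls of 23 (2 and 12), median -0.19, adjusted p = 0.090 with an estimated correlation, with LIMA1 higher at 2.32 ± 0.06 and CALD1 (-1.12 ± 0.06), ZYX (-0.92 ± 0.08) and VASP (-0.69 ± 0.09) lower. The amino acid response had 5 rises and 13 falls of 25 (5 and 13), median -0.14, adjusted p = 0.19 with an estimated correlation. SLC3A2 was at -1.13 ± 0.06, SLC7A5 at -0.86 ± 0.05, VLDLR at -0.73 ± 0.07 and ATF5 at 0.80 ± 0.09. Of the always reported genes, HSPB1 fell by 0.85 ± 0.06, HSP90AB1 by 0.38 ± 0.05, HSF1 by 0.29 ± 0.06 and DNAJB1 by 0.20 ± 0.06, HSP90B1 rose by 0.45 ± 0.09, and HSP90AA1 (0.0033 ± 0.05) and TRAP1 (-0.13 ± 0.06) did not pass. The other 18 lists had medians between -0.18 and 0.10, and median, mean and test differed in sign for heat shock, unfolded protein response, glycolysis, ERK, glucocorticoid receptor, alveolar, leukocyte and endothelial lists. Without _x_at and _s_at probe sets the calls of LUM, FAS, GDF15, AURKA and TAGLN ended, with changes between -0.18 and 0.28. The amino acid call ended too (camera adjusted p = 0.70). With the mean of a gene's probe sets HSP90AB1 was at -0.0091 (adjusted p = 0.95) and HSF1 at -0.13 (adjusted p = 0.17), and HSP90AA1 passed as a fall (-0.16, adjusted p = 0.043). DNAJB1 no longer passed with array medians subtracted (adjusted p = 0.075), without replicate 3 of the vehicle (0.0568) or without replicate 2 of the 10 nM arrays (0.0573).

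The doses at 48 h were compared directly, with the same difference in control probe sets between the arrays. Dose is therefore not separated here from whatever else sets the 10 nM arrays apart. Inflammatory and NRF2 genes were higher at 40 nM than at 10 nM. Of 21 NF-kB genes 18 were higher and 0 lower (18 and 0 adjusted over the list alone), with a median log2 difference of 0.92, and IL1A (2.43 ± 0.14), CXCL1 (2.06 ± 0.08), CCL2 (2.05 ± 0.09) and CCL20 (2.02 ± 0.10) differed most. Of 24 NRF2 targets 15 were higher and 1 lower (18 and 1), median 0.17, with HMOX1 at 1.02 ± 0.06, PGD at 0.97 ± 0.06, GCLM at 0.59 ± 0.05 and ABCC3 at 0.41 ± 0.05. These 2 calls held with an estimated correlation.

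Between the doses 5211 genes differed (limma), 2345 higher and 2866 lower at 40 nM, 228 and 149 by at least 2-fold. The groups did not overlap for 5163 of these called genes. HGD, an enzyme of tyrosine breakdown, was higher by 4.20 ± 0.10, TM4SF20 by 3.94 ± 0.22, TSPAN7 by 3.91 ± 0.12, RNF128 by 3.86 ± 0.16 and CDH6 by 3.85 ± 0.10. RNF128 was near background at 10 nM (2.99), so its difference is a lower bound. EDIL3 (-5.28 ± 0.08), FPR2 (-3.66 ± 0.10), SPARC (-3.43 ± 0.08), IFI27 (-3.23 ± 0.16) and RGS4 (-3.14 ± 0.19) were lower.

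Of the other lists called between the doses, heat shock genes had 13 higher and 1 lower of 25 (16 and 1 adjusted over the list alone), median 0.20, adjusted p = 0.17 with an estimated correlation. DNAJB6 was at 1.67 ± 0.09, HSPB1 at 0.94 ± 0.06, STIP1 at 0.58 ± 0.07 and HSPA2 at -0.47 ± 0.08. The amino acid response had 4 higher and 14 lower of 25 (5 and 15), median -0.29, adjusted p = 0.17 with an estimated correlation. TRIB3 was at -1.18 ± 0.05, CHAC1 at -1.14 ± 0.10, NUPR1 at -0.87 ± 0.10 and CTH at -0.83 ± 0.13. The p53 targets had 11 and 2 of 23 (12 and 3), median 0.18, adjusted p = 0.66 with an estimated correlation. CDKN1A was at 0.60 ± 0.06, PHLDA3 at 0.52 ± 0.06, SESN1 at 0.42 ± 0.08 and BAX at -0.42 ± 0.09. Proteasome subunits had 2 and 16 of 27 (2 and 18), median -0.17, adjusted p = 0.43 with an estimated correlation, with PSMC3 at -0.43 ± 0.06 and PSMA7 at -0.41 ± 0.06. Mesenchymal genes had 11 and 4 of 24 (12 and 4), median 0.12, adjusted p = 0.47 with an estimated correlation, with ZEB2 at 1.62 ± 0.14, THBS1 at 1.54 ± 0.08 and fibronectin FN1 at 1.41 ± 0.06.

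Fibroblast markers had 4 higher and 0 lower of 12 (4 and 0 adjusted over the list alone), median 0.16, adjusted p = 0.17 with an estimated correlation, with LUM at 2.61 ± 0.15 (a lower bound, from 2.92 at 10 nM) and collagen COL1A1 at 0.78 ± 0.12. THY1 and ACTA2 also passed as higher. THY1 did not with the compared groups alone (limma adjusted p = 0.072), without replicate 1 of the 10 nM arrays (0.088) or without replicate 3 of the 40 nM arrays (0.080). ACTA2 did not with the mean of its probe sets (0.018, limma adjusted p = 0.92). Actin and SRF targets had 10 and 1 of 23 (10 and 2), median 0.066, adjusted p = 0.37 with an estimated correlation. ANKRD1 was at 1.04 ± 0.12, CALD1 at 0.95 ± 0.06, CNN3 at 0.77 ± 0.07 and LIMA1 at -2.53 ± 0.06. G2/M genes had 1 and 10 of 27 (1 and 10), median -0.14, and interferon-stimulated genes 2 and 9 of 23 (2 and 9), median -0.15, both with adjusted p = 0.73 with an estimated correlation. PTTG1 was lower by -0.51 ± 0.05 and AURKB by -0.46 ± 0.06, and IFI6 by -2.39 ± 0.09, BST2 by -1.51 ± 0.22 and IRF7 by -0.63 ± 0.08. The G2/M call was kept in 2 of 6 fits that left out an array, the interferon call in 3, the fibroblast call in 4 and the actin call in 5. Median, mean and test differed in sign for HSP90 clients and epithelial genes. Without _x_at and _s_at probe sets 5 of the 11 list calls were made, and the calls of IL1A, LUM, ABCC3, CDC25C and PSMD4 ended.

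The 10 nM and 40 nM comparisons at 48 h share their vehicle arrays. They had 2032 calls in the same direction, 1133 higher and 899 lower, where independent lists would share 301 and 252, and 359 in opposite directions. The correlation of log2 changes across genes, which are not independent replicates, was 0.46. In 100 simulations of unchanged groups against shared controls it was 0.50. That is the correlation of noise alone, so the 2 values do not tell whether the real one holds an excess. The covariance was 0.0494 against a simulated 0.0058, a difference of 0.0436 after the simulated noise of shared controls is taken off. With 3 vehicle arrays the controls cannot be split into groups of 2, so part of the excess of shared calls may come from the shared controls.

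Vehicle cells at 48 h and at 24 h differed for 13975 genes (limma), 13313 higher and 662 lower at 48 h, with a median log2 difference over all genes of 0.35, which also holds any step between normalization runs. The share called higher was 95.3%, and it became 51.7% with loess between arrays, 25.5% with array medians subtracted and 48.1% with all arrays quantile-normalized together, where the median difference was -0.001, -0.145 and -0.018. The groups did not overlap for 13266 of the called genes, to which a step between the runs can also lead. NRF2 targets (24 of 24 higher, also over the list alone, median 0.54) and NF-kB genes (17 higher and 2 lower of 21, also over the list alone, median 1.06) were called, with adjusted p = 0.14 with an estimated correlation for the first and adjusted p = 0.91 with an estimated correlation for the second. The NF-kB call was also lost without the dimmest 40% of genes (camera adjusted p = 0.057), with array weights (0.11) and without _x_at and _s_at probe sets (median 0.49, 0.34). Median, mean and test differed in sign in 12 of the 26 lists, and no gene is named for this comparison.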

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

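The tests weighed here for the 10 nM arrays, the cell cycle and the inflammatory genes were chosen only after those results were seen, as were the counts of other splits of the arrays.

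The effect of 40 nM differed between 48 h and 24 h, by a test of that difference, for 10 named genes. The log2 change at 48 h minus that at 24 h was 3.33 for PTX3, 2.96 for CCL5, 2.82 for MAFF, 2.73 for G0S2 and 2.72 for BCL2A1. For HPD it was -3.43, for GREM1 by -2.79, for CDKN1C by -2.53, for UGT1A6 by -2.52 and for CTH by -2.47. The lists that differed had median differences of 0.91 for G2/M, 0.75 for G1/S, 1.18 for NF-kB genes, 0.40 for interferon-stimulated genes, 0.42 for ERK output, 0.32 for the amino acid response, 0.22 for apoptosis regulators, 0.20 for p53 targets and 0.18 for cholesterol synthesis. They were -0.44 for NRF2 targets, -0.31 for heat shock, and -0.11 for both autophagy and oxidative phosphorylation (-0.105 and -0.107). With an estimated correlation 4 of these 13 list calls held, those of G1/S, G2/M, NF-kB and NRF2, and 9 were lost.

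Signals were also seen outside the genes compared. Of the 3 control probe sets for 18S, the 3' one was 1.08 higher at 10 nM than in vehicle at 48 h on the log2 scale, with 1.13 for the 5' and 0.53 for the middle one. Probe sets without a gene symbol were called 1015 times at 24 h and 607 times at 48 h with 40 nM, and 1215 times at 10 nM, of 11721 tested.

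The first pattern weighed is the 10 nM arrays standing apart: RNA labelled apart from that of the other arrays at 48 h is consistent with the poly-A controls, whose median difference was -2.02. Such labelling is argued against as the cause of the 91 genes changed at least 4-fold at 10 nM, since for 69 of them the 24 h vehicle arrays, which carry the spikes, lay nearer to 10 nM than to vehicle at 48 h. An effect that grows with dose is argued against for that set as well, since 20 of the 91 had at least 0.5 of the change at 40 nM. Even so, 49 of the 91 changed in the same direction and were called there. The 91 were picked by their change at 10 nM, on arrays that also differ in their controls. The count therefore does not weigh an effect of dose on other genes. Cells of another stock stay open: of 33 measured chromosome Y genes 3 were lower at 10 nM (RPS4Y1 by -3.64, EIF1AY by -2.03, TXLNGY by -0.66) and 0 higher (Fisher exact p = 0.79). EIF1AY lay at 2.93 at 10 nM, near background, so its fall is a lower bound in size. All 3 were also lower in the 24 h vehicle than in the 48 h vehicle after centring. RPS4Y1 was lower by 4.14, EIF1AY by 1.995 and TXLNGY by 0.72. None of the 3 passed at 40 nM and 48 h (limma adjusted p = 0.99, 0.41 and 0.92). Only 1 of the 33 lay above the median level of all genes, so the Fisher test had little power and cannot decide. That test had 2 definitions, and the first, on Y genes above the median level of all genes, left 1 gene, RPS4Y1, so the second was chosen after the first result was seen.

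The second pattern is that cell cycle lists fell at 24 h and not at 48 h. A step shared by the arrays of a time drops out of a difference of effects, so joint normalization could hardly move it and does not weigh separate normalization. The median G2/M difference of effects was 0.91 as deposited. It was 0.90 after quantile normalization of all arrays together (quartiles 0.77 and 1.06). Vehicle cells that cycle less at 48 h, as the whole cause, stay open. After joint quantile normalization the vehicle G2/M median differed by -0.20, smaller in size than the 0.90. That value compares levels across times and depends on the scaling. The vehicle median over all genes was 0.35 as deposited and -0.145 with array medians subtracted, so the value cannot decide. Different cultures or preparations at the times cannot be told apart from time, and 526 genes differed between the vehicle groups by 1 or more after centring. Recovery of cycling with time, the biological explanation, stays open and untested.

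The third pattern is the larger rise of inflammatory genes at 48 h. Separate normalization was not weighed by joint quantile normalization here either, for the same reason. The median difference of effects was 1.23 after it (quartiles 0.48 and 1.58). Leukocytes among the cells are argued against by a median change of their markers of -0.043 at 48 h and 40 nM, with PTPRC at 0.096 (adjusted p = 0.57), although CD14 rose by 0.86 and ITGAM by 1.21. Different cultures at the times stay open here too, and a response to geldanamycin that builds up with time was not tested.

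Other splits of the 6 arrays of a comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. For genes, only 1 split, the real one, gave as many in each comparison: 6222 against at most 1 at 24 h, 5204 against 0 at 10 nM, 4207 against 0 at 40 nM and 48 h, 5211 against 0 between doses and 13975 against 0 between vehicle groups. For lists, 1 split gave as many at 24 h (13, highest other 11), at 10 nM (8, highest other 7) and between doses (11, highest other 9), 3 at 40 nM and 48 h (9, highest other 10) and 4 between vehicle groups (2, highest other 5).

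For the difference of effects, 3 of 100 regroupings gave as many genes as the real 3420. The highest other count, 6702, came from swapping the labels of all arrays at 48 h, which adds the effects at the 2 times, and the next was 3438, from a split that kept the 24 h groups and mixed those at 48 h. For its 13 lists 6 of 100 gave as many, the highest 16, so chance is not excluded. For the 2461 shared calls of 40 nM at both times 1 of 100, the real one, was as large (highest other 306), and for the 2032 shared calls of both doses 3 of 100 (highest other 2818, from exchanging whole groups). Mixing treated and vehicle arrays puts the treatment effects into the residual spread, which holds most of these counts at 0. They therefore do not exclude chance for a difference between the effects or for the shared calls.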

How the results depend on the processing

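Quantile normalization of all arrays together, fits without the 10 nM arrays and fits without the 526 genes were chosen only after the data were seen. Fold thresholds and list methods change a count by construction; for the other values below the cause was not tested unless it is given.

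With a change of at least 2-fold required, 548 genes changed at 24 h, 470 at 10 nM, 240 at 40 nM and 48 h, 377 between doses, 1072 between vehicle groups and 365 in the difference of effects. With an estimated correlation 6 lists were called at 24 h, 0 at 10 nM, 2 between doses, 0 between vehicle groups and 4 in the difference of effects. Fry called 22 lists at 24 h, 15 at 10 nM, 16 at 40 nM and 48 h, 17 between doses and 26 between vehicle groups.

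The vehicle comparison moved most often. It had 8255 genes and 8 lists with cyclic loess between arrays, 8807 and 11 with array medians subtracted, 9230 and 4 without the dimmest 40% of genes (fewer genes tested), and 8451 and 4 with quantile normalization of all arrays together. Its lists numbered 4 with the mean of a gene's probe sets, 4 with array weights and 6 with the arrays of the compared groups alone. Array weights gave 8036 genes at 10 nM, 5851 in the difference of effects and 3092 shared calls of both doses. Without the dimmest 40% of genes 7 lists were called between doses.

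Without _x_at and _s_at probe sets 5 lists were called between doses, 7 in the difference of effects, and 1625 calls were shared by 40 nM at 24 h and 48 h. Some genes then measured by another probe set had a value of the other sign, and none of these values passed (limma adjusted p between 0.087 and 0.98). They were, at 24 h, DLEU2 (0.0087), ASNS (0.036), GINS2 (0.073) and TPM1 (0.13), and at 10 nM GDF15 (-0.11). At 40 nM and 48 h they were KLF2 (0.048) and GDF15 (-0.22). In the difference of effects they were ASNS (-0.23), AKR1C2 (0.34) and GINS2 (-0.047). Of 2 values near 0, HSP90AA1 at 10 nM was -0.00062 with loess, -0.16 with the probe set mean, where it passed (adjusted p = 0.043), and -0.020 with joint quantile normalization, and HSP90B1 at 40 nM and 48 h was -0.0049 with array medians subtracted and -0.0075 with joint quantile normalization.

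Leaving out each array in turn gave 5632 to 6187 genes and 13 to 15 lists at 24 h, 4278 to 4929 and 8 to 10 at 10 nM, 3329 to 3493 and 9 to 12 at 40 nM and 48 h, 4231 to 4853 and 8 to 11 between doses, 12755 to 13438 and 2 to 7 between vehicle groups (7 without replicate 3 of the 24 h vehicle), and 2820 to 3527 and 12 to 13 in the difference of effects. Shared calls ranged from 2021 to 2504 for 40 nM at both times and from 1580 to 1914 for both doses. HSP90AA1 at 10 nM ranged from -0.0019 to 0.011 and HSP90B1 at 40 nM and 48 h from -0.059 to 0.11. With the replicate number as a block, 5974, 4920, 3864, 4894, 13782 and 3052 genes changed at 24 h, at 10 nM, at 40 nM and 48 h, between doses, between vehicle groups and in the difference of effects, with 13, 8, 9, 11, 2 and 13 lists and 2260 and 1875 shared calls. The residuals did not show whether the numbers pair the arrays. Of 30 same-number pairs 10 had a correlation over 0.1, with values from -0.46 to 0.50. Pairs with different numbers ranged from -0.58 to 0.48.

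Of 304 results for named genes, 292 kept direction and side of the threshold with the probe set mean, 296 with array medians subtracted, 303 with loess and 302 with joint quantile normalization. Without _x_at and _s_at probe sets 195 did, 24 no longer passed and 10 had the other sign without passing. The rest of the 304 had no probe set left and were not tested there. Of simulated changes of 0.25, 10% were recovered, with far fewer changed genes than were called in the real data. Recovery by signal level was not examined.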

Other observations

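The lists of immediate early, MHC class II, complement and xenobiotic metabolism genes, and the genes named from them, were chosen only after their values were seen, so only counts, medians and single values are given.

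Complement genes encode proteins of innate defence. Of 13 measured, 9 rose and 0 fell at 24 h (median log2 change 1.01), 8 and 0 at 40 nM and 48 h (0.66) and 5 and 0 at 10 nM (0.26). C3 rose by 2.03 ± 0.05 at 24 h, 1.89 ± 0.05 at 40 nM and 48 h and 1.52 ± 0.05 at 10 nM (SE, 3 arrays per group). CFB rose by 1.19 at 24 h and 1.79 at 48 h with 40 nM, and C1S by 1.26 and 1.21. MHC class II genes, which present antigen, went apart: of 9 measured, 4 fell and 0 rose at 24 h (median -0.42), while 6 rose and 0 fell at 10 nM (1.03) and 2 rose and 0 fell at 40 nM and 48 h (0.15). HLA-DPA1 changed by -0.95 at 24 h, 3.06 at 10 nM and 0.59 at 40 nM and 48 h, and CD74, the invariant chain, rose by 2.41 ± 0.23 at 10 nM.

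Genes of xenobiotic metabolism had 23 rises and 1 fall of 29 at 24 h (median 0.54), 7 and 6 at 10 nM (0.0034) and 11 and 2 at 40 nM and 48 h (0.15). The sulfotransferases SULT1A1 and SULT1C2 rose at 24 h by 1.59 and 1.68, at 10 nM by 2.55 and 2.66 and at 40 nM and 48 h by 1.20 and 1.08. CYP1B1 changed by 0.49 at 24 h, -2.81 at 10 nM and -0.60 at 40 nM and 48 h. Of 24 immediate early genes 12 fell and 2 rose at 24 h (median -0.34), 9 and 5 at 10 nM (-0.091) and 10 and 4 at 40 nM and 48 h (-0.099). IER2 fell by 1.45 ± 0.05 and JUN by 1.02 ± 0.05 at 24 h, and MYC fell by 0.67 at 24 h, 0.93 at 10 nM and 0.50 at 40 nM and 48 h.

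For the 526 genes whose vehicle levels differed between the times by 1 or more after centring, the position of 10 nM between the 24 h vehicle (0) and the 48 h vehicle (1) had a median of 0.44, with quartiles of 0.13 and 0.88, and that of 40 nM at 48 h a median of 1.03. For the 101 genes that differed by 2 or more, the medians were 0.25 (quartiles 0.068 and 0.58) and 1.05.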
